A study of Yarrowia lipolytica with 35 samples.

How the data were processed

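RNA was measured by sequencing in 35 libraries from Yarrowia lipolytica grown in bioreactors. Per the labels' protocols, cells were broken with beads, total RNA was extracted with a column kit, and strand-specific libraries were made from poly(A) RNA. The labels name the strain, carbon source, phase, pH, hour and replicate of each library, and each library was placed in its group and given its replicate number from them. The authors deposited a table of raw counts of reads per gene, named as such in the file headers, and a table of log2 values. The submitters' processing notes name BWA 0.7.12-r1039, featureCounts 1.5.1 and edgeR without their roles; the genome build and the strand setting of the counting are not given in the sources used here. Genes that overlap or share near-identical sequence, such as members of the ALK, POX and YHT families, can therefore share reads in a way that was not examined. The deposited log2 values matched log2(FPKM + 1) computed from the deposited counts and the effective lengths in the count table, with a factor per library, within 0.02 for 99.9% of values, against 85.4% with the full lengths. All 35 columns of either table were assigned by name, and 0 columns were unused.

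The count table holds 7132 genes: 6448 with protein-coding locus tags, 639 noncoding ones, which include tRNA and rRNA genes, and 45 mitochondrial ones. Totals per library were 6.7 megareads (M) to 25702157 reads. The 10 genes with most reads took 5.0 to 7.5% of a library, and mitochondrial genes took 0.0014 to 0.0653%. No replicate pair agreed within sampling noise (lowest chi-square per gene 3.4 over 34 pairs), so each library was counted as 1 replicate. A gene with 10 reads in a library of median depth varies by about 3 reads from counting alone, so levels near the floor are uncertain, and some are given as reads.

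Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 12 groups, which left 6537 (6295 coding, 227 noncoding and 15 mitochondrial), and libraries were scaled by TMM, with factors from 0.865 to 1.176. A quasi-likelihood model with 1 coefficient per group and robust estimation was fitted to all libraries, with 23 residual degrees of freedom and a biological coefficient of variation of 14.8%. Each comparison is the mean of the differences over its strata: glycerol minus glucose in growth phase (2 strata) and at 32 h (4), pH 3.5 minus pH 5.5 (4), 32 h minus growth at pH 5.5 (4) and DSM-21175 minus DSM-3286 (6). A further 6 contrasts test how these changes differ between phases, carbon sources or strains. For the change with carbon source, the difference between phases uses only the 32 h libraries at pH 5.5, not the mean over both pH values. P-values were adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p under 0.05 is a call. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled to the TMM-adjusted library total.

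The gene lists, the test of each comparison, the alternatives and the rule for named genes were fixed before the data were examined. The 14 lists tested with limma 3.58.1's camera cover glycerol and dihydroxyacetone metabolism, glycolysis and gluconeogenesis, the pentose phosphate pathway, erythritol and mannitol metabolism, the tricarboxylic acid cycle and pyruvate entry, the glyoxylate cycle, citrate transport, fatty acid synthesis, triacylglycerol synthesis and lipolysis, peroxisomal beta-oxidation, alkane-inducible cytochromes P450, extracellular proteases and lipases, hexose transporters, and nitrogen assimilation and purine salvage. Regulators and pH-related single genes form a further list given as counts. Camera ran on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the 14 lists of a comparison, and again with an estimated correlation. List symbols were paired with locus tags from memory of published names before the data were examined, with no source at hand. Of 122 listed tags 121 are in the count table, and only RIM101 and MHY1 could be checked against symbols in the files, so that the identity of the other list genes is unverified. The reference gene table matched 0 IDs and was not used. A further 12 lists defined by product descriptions, such as ribosomal proteins, proteasome and autophagy, were not analysed here. The 71 symbols of the deposited log2 table were paired with IDs by their values, after the files were seen; the submitters chose them, so their counts are not independent evidence of a direction.

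Named genes are, per comparison, up to 4 called members of each list with the largest change, up to 5 higher and 5 lower among called genes with a name, the same sign in every stratum and a mean log2 CPM of 3 or more, up to 2 higher and 2 lower without a name, and GUT1, GUT2, CEX1, EYK1 and AXP1 in any case. For differences of changes they are up to 5 called named genes of each sign. XPR2 is not analysed here. Genes with reads in 1 strain only were chosen after their values were seen.

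On simulated counts for the 6537 genes, with 100 genes changed 2-fold and 100 changed 4-fold per contrast, the 5 comparisons recovered 94, 93, 98, 96 and 94 of the 2-fold changes and 98, 100, 99, 99 and 99 of the 4-fold ones. The 6 differences, in the order substrate by phase, substrate by pH, strain by substrate in growth and in stationary phase, strain by pH and strain by phase, recovered 78, 91, 73, 79, 84 and 94 of the 2-fold changes and 92, 90, 88, 93, 90 and 94 of the 4-fold ones. False calls were 5 to 13 per contrast. In 14 simulated lists of 10 genes, in the substrate comparison of growth phase, camera called 3 of 3 shifted lists and 1 unshifted list. The simulated genes varied independently of each other and few were changed. In the data, estimated correlations within lists reached 0.486, and 43.2 to 86.1% of genes were called in the 5 comparisons. The simulated recoveries and false calls therefore do not carry over directly to these data. Alternatives were RLE scaling, no expression filter, DESeq2 1.42.0, limma on the deposited log2 values, a fit of only the libraries compared, the replicate number as a block, a 2-fold threshold and leaving out each library in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and robust estimation used statmod 1.5.0.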

Results

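The data are RNA sequencing of Yarrowia lipolytica, an oleaginous yeast that uses glucose, glycerol, alkanes and fatty acids and can secrete citrate and polyols, grown in bioreactors on glucose or glycerol as the sole carbon source. The 35 libraries fall into 12 groups of the strains DSM-3286 and DSM-21175. Each strain was sampled on both carbon sources in growth phase at pH 5.5, after 8 h on glycerol and 12 h on glucose, and in nitrogen-limited stationary phase after 32 h at pH 5.5 and at pH 3.5. Each group holds 3 replicates, described by the submitters as biological triplicates, except DSM-3286 on glucose in stationary phase at pH 5.5, with 2. The count table lists reads for 7132 genes, and the total per library had a median of 12.55 M (megareads) and a lowest value of 6.7 M. By group, the totals in DSM-3286 were 11.91 to 13.22 M on glucose in growth phase, 12.93 to 14.15 M on glucose at 32 h and pH 5.5, and from 8.88 M up to 25702157 reads at pH 3.5. On glycerol in DSM-3286 they were 9.21 to 24.26 M in growth phase, 6.7 to 11.47 M at 32 h and pH 5.5, and 10 to 15.06 M at pH 3.5. In DSM-21175 they were 10.49 to 13.52, 12.48 to 14.94 and 11.97 to 19.71 M on glucose and 9.22 to 12.55, 11.64 to 11.91 and 13.48 to 17.19 M on glycerol, in the same order. Levels are given as CPM (counts scaled to the library total, mean ± SD over the replicates of a group) and changes as log2 fold changes ± SE. A gene is called changed when it passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at the 0.05 level, and the fold change of a comparison is the mean over its strata.

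The first principal component of the log2 CPM values held 47.5% of the variance and separated growth phase from stationary phase. The second held 22.7% and separated the strains. Replicates of a group correlated with a Pearson r across genes between 0.9787 and 0.9984, with a median of 0.99615 over 34 pairs. In DSM-21175, 5 libraries correlated less with both replicates than those did with each other, by more than 0.005 in r. These were replicate 3 on glucose in growth phase, replicate 3 on glucose at 32 h and pH 5.5, replicate 2 on glycerol in growth phase, and replicate 3 on glycerol at 32 h at both pH values. In these libraries 462, 550, 341, 376 and 368 genes lay at least 2-fold from the replicates, for glucose growth, glucose pH 5.5, glycerol growth, glycerol pH 3.5 and glycerol pH 5.5 in that order. All libraries are kept in the comparisons. A class of RNAs listed without protein-coding tags, here called noncoding, took 0.019 to 0.215% of the reads and moved with carbon source and pH, and its values stand beside each comparison.

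**Figure D1:**
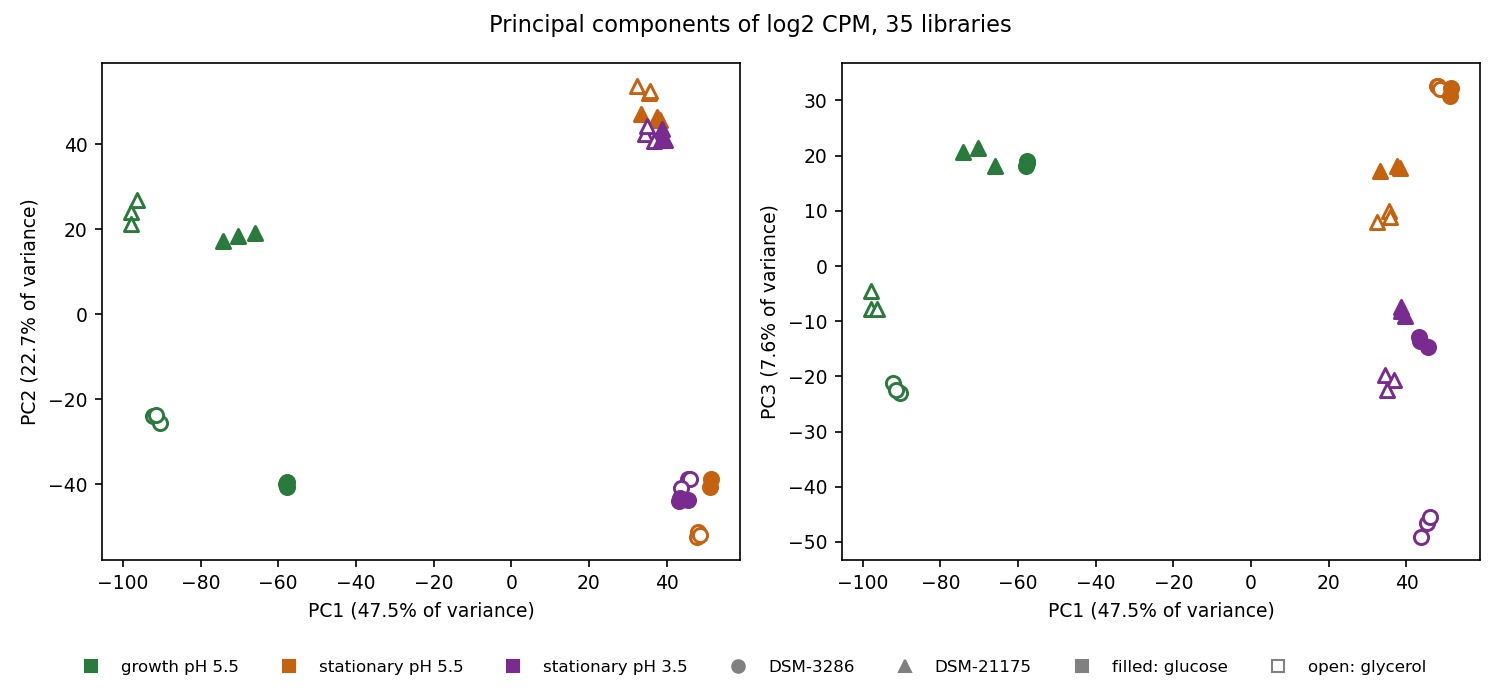
Scores of the 35 libraries (points) on principal components of log2 CPM, component 1 against component 2 on the left and against component 3 on the right, with colour for phase and pH, shape for strain and filling for carbon source. Component 1 (47.5% of the variance) parts growth from stationary phase, component 2 (22.7%) the strains and component 3 (7.6%) the pH values at 32 h.

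The first comparison addresses how growing cells on glycerol differ from growing cells on glucose. POX4 (YALI0E27654g), an acyl-CoA oxidase of peroxisomal beta-oxidation, was at 60.3 ± 3.18 CPM on glucose and 2.96 ± 0.608 CPM on glycerol in DSM-3286 and at 68.5 ± 19.3 and 5.75 ± 2.5 CPM in DSM-21175 (SD, n = 3 each), a log2 fold change of -3.94 ± 0.21. The extracellular lipase gene LIP8 (YALI0B09361g) went from 2140 ± 239 CPM on glucose to 6.69 ± 0.315 CPM on glycerol in DSM-3286 and from 643 ± 557 to 14 ± 5.18 CPM in DSM-21175, where LIP8 on glucose ranged from 11.7 to 1070 CPM between replicates. Glycerol kinase, GUT1 (YALI0F00484g), which starts glycerol use, was also lower on glycerol: 1140 ± 34.9 against 5000 ± 112 CPM in DSM-3286 and 609 ± 158 against 1050 ± 118 CPM in DSM-21175, with a log2 fold change of -1.46 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 2.67e-12).

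Of the 12 peroxisomal beta-oxidation genes tested, 12 fell on glycerol, with a median log2 fold change of -1.18 (limma's camera, Benjamini-Hochberg adjusted p = 1.88e-06; adjusted p = 0.0688 with an estimated correlation). Beside POX4 the acyl-CoA oxidase genes POX5 (YALI0C23859g, -3.42 ± 0.27), POX1 (YALI0E32835g, -2.91 ± 0.21) and POX6 (YALI0E06567g, -2.48 ± 0.15) changed most. Of the 12 alkane-inducible cytochrome P450 genes, 10 fell, 1 rose and 1 did not pass, with a median of -2.67 (camera adjusted p = 0.000455, limma with Benjamini-Hochberg; adjusted p = 0.0685 with an estimated correlation). On the deposited log2 values the median was -1.49 and the call of ALK8 (YALI0C12122g) was lost (-0.16, limma, Benjamini-Hochberg adjusted p = 0.209). ALK3 (YALI0E23474g) changed by -5.32 ± 0.37, ALK11 (YALI0C10054g) by -3.91 ± 0.26 and ALK5 (YALI0B13838g) by -3.84 ± 0.15, while ALK8 had at most 7 reads in any growth-phase library. In the glyoxylate cycle 4 of 5 genes fell, among them the citrate synthase gene CIT2 (YALI0E00638g) at -2.48 ± 0.18 and the malate synthase genes MLS2 (YALI0D19140g) at -2.49 ± 0.34 and MLS1 (YALI0E15708g) at -1.17 ± 0.12 (camera adjusted p = 0.0276, limma with Benjamini-Hochberg; adjusted p = 0.14 with an estimated correlation). Of 4 hexose transporter genes 3 fell and 1 did not pass. YHT1 (YALI0C06424g) changed by -2.70 ± 0.36 and YHT4 (YALI0E23287g) by -2.46 ± 0.14, and the list test gave a camera adjusted p = 0.0352 (limma with Benjamini-Hochberg; adjusted p = 0.14 with an estimated correlation). The remaining call was YHT2 (YALI0C08943g). It had at most 10 reads in any of these libraries and was lost without any of DSM-3286 glycerol growth replicates 1, 2 and 3, DSM-21175 glycerol growth replicates 2 and 3 or DSM-3286 glucose growth replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0566, 0.0531, 0.0902, 0.056, 0.0581 and 1 in that order). It was also lost with DESeq2 (Benjamini-Hochberg adjusted p = 0.0561). In triacylglycerol synthesis and lipolysis 5 of 9 genes fell, 1 rose and 3 did not pass, with DGA1 (YALI0E32769g), a diacylglycerol acyltransferase, at -1.27 ± 0.07 and the lipase gene TGL3 (YALI0D17534g) at -1.06 ± 0.09 (camera adjusted p = 0.0276, limma with Benjamini-Hochberg; adjusted p = 0.14 with an estimated correlation). Of 5 genes of nitrogen assimilation and purine salvage 4 fell and 1 did not pass, including glutamate synthase GLT1 (YALI0B19998g) at -1.12 ± 0.11 (camera adjusted p = 0.0276, limma with Benjamini-Hochberg; adjusted p = 0.0694 with an estimated correlation). The glutamate dehydrogenase gene GDH2 (YALI0E09603g) stood at -0.89 ± 0.09, with -1.84 in 1 strain and 0.06 in the other.

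Glycerol and dihydroxyacetone metabolism split in this comparison. The dihydroxyacetone kinase genes DAK2 (YALI0E20691g, -3.57 ± 0.42) and DAK1 (YALI0F09273g, -0.50 ± 0.11) fell with GUT1, the glycerol-3-phosphate dehydrogenase gene GPD1 (YALI0B02948g) rose by 0.69 ± 0.07, and the mitochondrial glycerol-3-phosphate dehydrogenase gene GUT2 (YALI0B13970g) stood at -0.01 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 0.962). In erythritol and mannitol metabolism 7 of 10 genes fell, 2 rose and 1 did not pass (camera adjusted p = 0.107, limma with Benjamini-Hochberg). The mannitol dehydrogenase gene SDR2 (YALI0D18964g) changed by -1.87 ± 0.13 and the erythrulose kinase gene EYK1 (YALI0F01606g) by -1.87 ± 0.57. The neighbouring erythritol genes EYI2 (YALI0F01628g) and EYD1 (YALI0F01650g) changed by -3.30 ± 0.54 and -2.84 ± 0.63, and by -4.62 and -4.10 without DSM-21175 glycerol growth replicate 3, without which the list passed at an adjusted p = 0.0462 (limma's camera, Benjamini-Hochberg). Of 4 extracellular protease and lipase genes 3 fell and 1 did not pass. Among the 3, the lipase gene LIP2 (YALI0A20350g) stood at -0.97 ± 0.27, with -2.45 in 1 strain and 0.51 in the other. Its call was lost in a fit of only the libraries compared (edgeR, Benjamini-Hochberg adjusted p = 0.0531). The list had an adjusted p = 0.101 and of 0.0186 without DSM-21175 glucose growth replicate 3 (limma's camera, Benjamini-Hochberg). Glycolysis and gluconeogenesis (3 higher, 5 lower, 5 not passing), the pentose phosphate pathway (2, 1 and 4), the tricarboxylic acid cycle (1, 2 and 12), citrate transport (1, 0 and 2) and fatty acid synthesis (4, 1 and 5) did not pass the list test (limma's camera, Benjamini-Hochberg adjusted p between 0.321 and 0.837). In these lists hexokinase HXK1 (YALI0B22308g) changed by -0.93 ± 0.10, the citrate carrier gene CTP1 (YALI0F26323g) by 0.66 ± 0.08 and the elongase gene ELO1 (YALI0F06754g) by 0.86 ± 0.14. TAL1 (YALI0F15587g), of the pentose phosphate pathway, was called at 0.17 ± 0.06, with -0.07 in 1 strain and 0.42 in the other. Its call was lost with RLE scaling (edgeR, Benjamini-Hochberg adjusted p = 0.108) and with DESeq2 (Benjamini-Hochberg adjusted p = 0.0835). The citrate exporter gene CEX1 (YALI0D20196g) stood at 0.41 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 0.079). It passed in a fit of only the libraries compared (adjusted p = 0.0249, edgeR with Benjamini-Hochberg).

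Of 7 regulators and pH-related genes 2 fell and 5 did not pass, with the pH-response transcription factor gene RIM101 (YALI0B13640g) at -1.23 ± 0.09. Of the 71 genes to which the deposited log2 table gives a symbol, 13 rose, 34 fell and 24 did not pass. The submitters chose these symbols on a basis not given in the sources used here, so they are not independent evidence of a direction. The largest rises with a symbol were TFC2 (YALI0F05104g, 1.32 ± 0.13), BUD20 (YALI0D13068g, 1.21 ± 0.09), REI1 (YALI0B08734g, 0.91 ± 0.09) and STP3 (YALI0B05478g, 0.88 ± 0.16). Without a name, YALI0B19492g fell by 7.82 ± 0.34 and YALI0B21472g rose by 4.87 ± 0.31. Over all 6537 genes tested, 2081 rose and 2008 fell on glycerol in growth phase. Of these, 361 of the rises and 623 of the falls were at least 2-fold (edgeR, Benjamini-Hochberg). The balance depends on scaling, with 1887 higher and 2281 lower with RLE scaling (edgeR, Benjamini-Hochberg). Of these calls 3967 had the same sign in both strains. Within each strain, 3618 genes in DSM-3286 and 3049 in DSM-21175 were called. Adjusted over the list alone, the counts were the same for every list except the glyoxylate cycle (1 higher, 4 lower) and nitrogen assimilation (0 higher, 5 lower). Of 227 noncoding genes 70 rose and 5 fell on glycerol with a median of 1.16 (0.63 on the deposited log2 values). Their share of reads in DSM-3286 was 0.0937 ± 0.0067% on glycerol against 0.047 ± 0.004% on glucose. The carbon sources were sampled 4 h apart in growth phase, so the comparison does not part carbon source from hour.

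The same question was put to stationary phase, where both carbon sources were sampled at 32 h. The hexose transporter gene YHT1 was at 1310 ± 123 CPM on glucose (n = 2) and 71.2 ± 11.3 CPM on glycerol (n = 3) in DSM-3286 at pH 5.5, and at 37.5 ± 40.2 and 9.43 ± 2.54 CPM in DSM-21175. There the glucose mean rests on replicate 3, with 84 CPM against 13.2 and 15.3 CPM in the others. Over the 4 strata of strain and pH, YHT1 changed by -2.85 ± 0.27 and YHT4 by -2.36 ± 0.11. POX4 changed by -2.04 ± 0.14 and the cytochrome P450 gene ALK9 (YALI0B06248g) by -2.33 ± 0.14. GUT1 differed by -0.40 ± 0.08, from 461 CPM on glucose to 333 CPM on glycerol over the strata (edgeR, Benjamini-Hochberg adjusted p = 0.00014). GUT2 stood at 0.01 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.977).

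All 12 beta-oxidation genes tested fell on glycerol at 32 h, with a median of -0.75 (limma's camera, Benjamini-Hochberg adjusted p = 3.28e-09; adjusted p = 0.0179 with an estimated correlation). POX6 changed by -1.37 ± 0.10 and the thiolase gene POT1 (YALI0E18568g) by -0.82 ± 0.10. Of the 12 cytochrome P450 genes 10 fell and 2 did not pass (camera adjusted p = 1.48e-06, limma with Benjamini-Hochberg; adjusted p = 0.00701 with an estimated correlation). ALK1 (YALI0E25982g) changed by -1.96 ± 0.29, ALK3 by -1.92 ± 0.26 and ALK5 by -1.59 ± 0.10. In nitrogen assimilation 4 of 5 genes fell, with glutamine synthetase GLN1 (YALI0F00506g) at -0.53 ± 0.10 and GLT1 at -0.52 ± 0.08 (camera adjusted p = 0.00681, limma with Benjamini-Hochberg; adjusted p = 0.0274 with an estimated correlation). These 3 lists were the ones of this comparison, and of the 29 list calls over all comparisons, that passed with an estimated correlation. In glycolysis and gluconeogenesis 7 of 13 genes fell and 6 did not pass, with phosphoenolpyruvate carboxykinase PCK1 (YALI0C16995g) at -1.46 ± 0.10, glucokinase GLK1 (YALI0E15488g) at -0.41 ± 0.05 and aldolase FBA1 (YALI0E26004g) at -0.38 ± 0.04 (camera adjusted p = 0.000835, limma with Benjamini-Hochberg; adjusted p = 0.122 with an estimated correlation). In the tricarboxylic acid cycle 6 of 15 genes fell and 9 did not pass, with citrate synthase CIT1 (YALI0E02684g) at -0.41 ± 0.07 (camera adjusted p = 0.0168, limma with Benjamini-Hochberg; adjusted p = 0.423 with an estimated correlation).

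In the glyoxylate cycle 4 of 5 genes fell at 32 h, led by CIT2 at -2.08 ± 0.14 (camera adjusted p = 0.00335, limma with Benjamini-Hochberg; adjusted p = 0.0833 with an estimated correlation). Of 9 genes of triacylglycerol synthesis and lipolysis 7 fell, 1 rose and 1 did not pass, with DGA1 at -0.78 ± 0.05 and TGL3 at 0.24 ± 0.06 (camera adjusted p = 0.00351, limma with Benjamini-Hochberg; adjusted p = 0.0588 with an estimated correlation). Of 4 hexose transporter genes 2 fell and 2 did not pass (camera adjusted p = 0.0168, limma with Benjamini-Hochberg; adjusted p = 0.122 with an estimated correlation). Erythritol and mannitol metabolism (4 higher, 2 lower, 4 not passing), glycerol metabolism (0, 2 and 3), the pentose phosphate pathway (2, 0 and 5), citrate transport (1, 0 and 2), fatty acid synthesis (1, 4 and 5) and extracellular proteases and lipases (0, 2 and 2) did not pass the list test (limma's camera, Benjamini-Hochberg adjusted p between 0.133 and 0.818). The median of citrate transport was -0.04 and its mean 0.07. The erythrose reductase gene ER10 (YALI0D07634g) was higher on glycerol by 0.58 ± 0.10 and the transketolase gene TKL1 (YALI0E06479g) by 0.32 ± 0.07. As a mean over the strata, CEX1 was higher on glycerol by 0.38 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 0.0213), and did not pass in a fit of only the libraries compared (adjusted p = 0.0556, edgeR with Benjamini-Hochberg). By stratum CEX1 ranged from -0.47 in DSM-3286 at pH 3.5 to 1.06 in DSM-21175 at pH 5.5. In the latter, glucose replicate 3 had 83.6 CPM against 229 and 213 CPM in the others. EYK1 stood at 0.68 ± 0.30 (edgeR, Benjamini-Hochberg adjusted p = 0.064). It passed without DSM-21175 glycerol pH 5.5 replicate 3 (0.81, adjusted p = 0.00201), glycerol pH 3.5 replicate 1 (0.78, adjusted p = 0.0355) or glucose pH 5.5 replicate 3 (0.75, adjusted p = 0.0488). The acid protease gene AXP1 (YALI0B05654g) stood at -0.06 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.67).

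Among genes with a symbol in the deposited log2 table, IXR1 (YALI0B04510g, 0.64 ± 0.07), HAC1 (YALI0B12716g, 0.32 ± 0.05) and MET32 (YALI0F03157g, 0.33 ± 0.07) were higher on glycerol at 32 h. AZF1 (YALI0A16841g) was higher by 0.98 ± 0.27 and by 0.62 without DSM-21175 glycerol pH 3.5 replicate 2, when it did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0762). Of the 71 genes with a symbol 14 rose, 21 fell and 36 did not pass, and of 7 regulators and pH-related genes 1 rose, 3 fell and 3 did not pass. Without a name, YALI0F08129g fell by 4.69 ± 0.22 and YALI0C13024g rose by 2.73 ± 0.33. In all, 1448 genes rose and 1375 fell, 139 and 171 of them at least 2-fold. Of the called genes 1400 had the same sign in all 4 strata (edgeR, Benjamini-Hochberg). Within DSM-3286 the test called 2339 genes at pH 5.5 and 2793 at pH 3.5. Within DSM-21175 it called 776 and 1029. Adjusted over the list alone, the counts were the same for every list except glycolysis (0 higher, 8 lower) and erythritol and mannitol metabolism (5 higher, 3 lower). Of 227 noncoding genes 106 rose and 1 fell on glycerol, with a median of 1.61 (0.87 on the deposited log2 values). In DSM-3286 at pH 5.5 their share of reads was 0.187 ± 0.025% on glycerol and 0.064 ± 0.0028% on glucose. The strata of DSM-21175 include 3 of the libraries that stood apart.

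**Figure D2:**
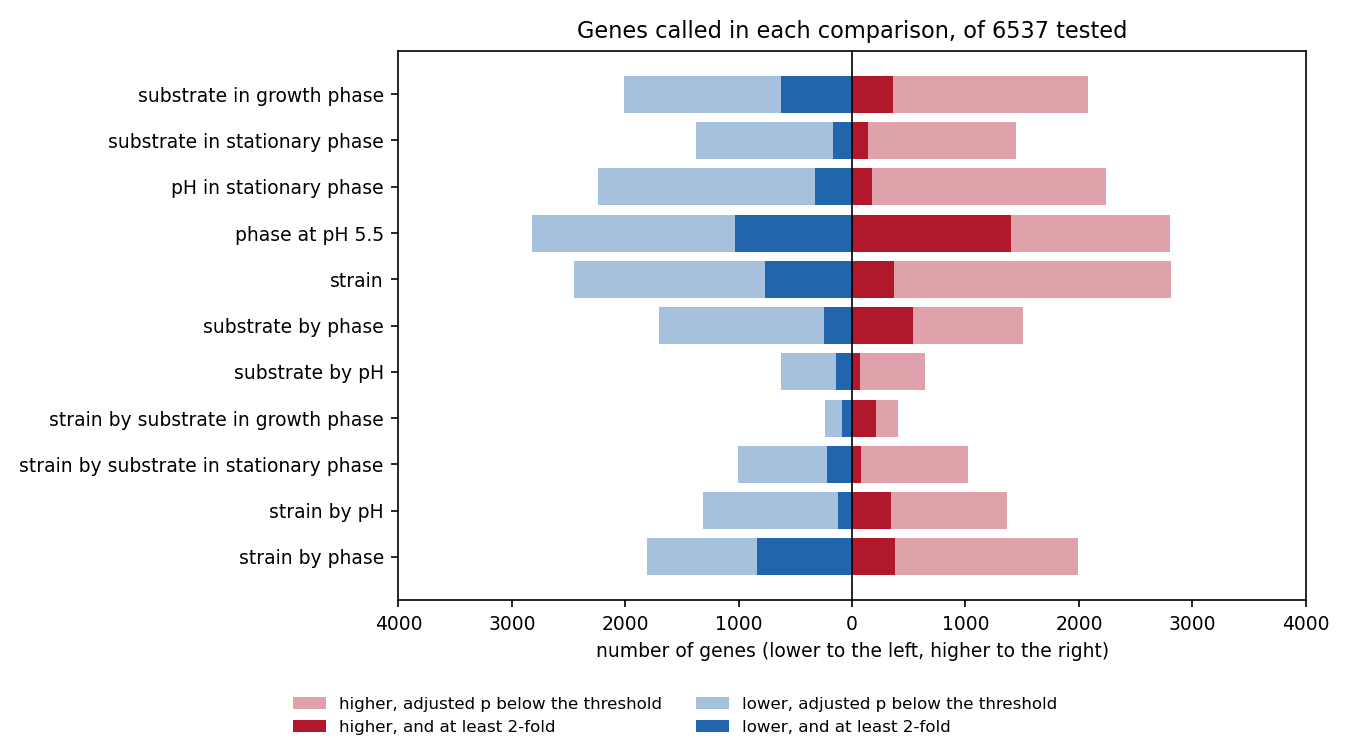
Number of genes called higher (bars to the right) and lower (bars to the left) in each comparison and each difference of changes by edgeR with Benjamini-Hochberg adjustment, with the part that changed at least 2-fold in the darker shade. Of 6537 genes tested, 5628 differed between stationary and growth phase and 2823 between glycerol and glucose at 32 h.

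The third comparison addresses the pH of the culture in stationary phase, 3.5 against 5.5. The citrate exporter gene CEX1 was far lower at pH 3.5: on glycerol in DSM-3286 it stood at 417 ± 64.2 CPM against 9900 ± 21.4 CPM at pH 5.5 (SD, n = 3 each), on glucose at 578 ± 234 against 7280 ± 11.5 CPM (n = 3 and 2), and in DSM-21175 at 57.7 ± 7.76 against 364 ± 43.8 CPM on glycerol. Over the 4 strata of strain and carbon source it changed by -3.24 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 6.84e-17). RIM101, which acts in the response to alkaline pH in fungi, changed by -2.06 ± 0.06. MHY1 (YALI0B21582g), a zinc finger protein gene linked to the switch from yeast to hyphal growth, changed by -1.50 ± 0.19. The acid extracellular protease gene AXP1 was lower at pH 3.5 by -1.87 ± 0.10, with 5.45 ± 0.892 CPM at pH 3.5 and 84.2 ± 11.6 CPM at pH 5.5 on glycerol in DSM-3286. Malate dehydrogenase MDH1 (YALI0D16753g) rose by 1.44 ± 0.17 and 6-phosphogluconate dehydrogenase GND1 (YALI0B15598g) by 0.96 ± 0.06.

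In glycolysis and gluconeogenesis 8 of 13 genes rose at pH 3.5 and 5 did not pass, with PCK1 at 1.38 ± 0.11, phosphoglycerate kinase PGK1 (YALI0D12400g) at 0.78 ± 0.06 and triosephosphate isomerase TPI1 (YALI0F05214g) at 0.66 ± 0.04 (limma's camera, Benjamini-Hochberg adjusted p = 0.0104; adjusted p = 0.758 with an estimated correlation). In the tricarboxylic acid cycle 11 of 15 rose, 1 fell and 3 did not pass, with KGD2 (YALI0E16929g) of the 2-oxoglutarate dehydrogenase complex at 0.93 ± 0.07 and succinate-CoA ligase LSC1 (YALI0D04741g) at 0.59 ± 0.05 (camera adjusted p = 0.0104, limma with Benjamini-Hochberg; adjusted p = 0.827 with an estimated correlation). In the pentose phosphate pathway 5 of 7 rose, 1 fell and 1 did not pass, with 6-phosphogluconolactonase SOL3 (YALI0E11671g) at 0.72 ± 0.04 (camera adjusted p = 0.0482, limma with Benjamini-Hochberg; adjusted p = 0.758 with an estimated correlation). This list did not pass when any of 15 libraries was left out singly, with an adjusted p of up to 0.066 without DSM-21175 glycerol pH 5.5 replicate 3 (limma's camera, Benjamini-Hochberg). The other lists did not pass (limma's camera, Benjamini-Hochberg adjusted p between 0.187 and 0.975).

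Fatty acid synthase FAS1 (YALI0B15059g) was lower at pH 3.5 by -1.0 ± 0.08, with 3 of 10 fatty acid synthesis genes higher, 3 lower and 4 not passing. In beta-oxidation 8 genes rose, 2 fell and 2 did not pass. The cytochrome P450 genes divided into 3 higher, 3 lower and 6 not passing, with ALK3 at -1.68 ± 0.26. ALK8 was at 26.8 ± 1.84 CPM at pH 3.5 and 2.15 ± 1.09 CPM at pH 5.5 on glycerol in DSM-3286. In the glyoxylate cycle 4 of 5 rose, with CIT2 at 1.37 ± 0.14. The call of MLS1 (0.20) was lost with only the libraries compared (edgeR, Benjamini-Hochberg adjusted p = 0.0523). It was also lost in many fits that left out 1 library, at 0.14 without DSM-21175 glycerol pH 3.5 replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.122). Erythritol and mannitol metabolism had 4 higher, 4 lower and 2 not passing: SDR2 rose by 0.78 ± 0.10, while EYD1 and EYK1 changed by -2.05 ± 0.40 and -1.19 ± 0.29, with opposite signs on the 2 carbon sources in DSM-3286. EYK1 there went from 110 ± 17.8 to 27.7 ± 1.58 CPM on glycerol and from 32.4 ± 1.75 to 85.2 ± 5.37 CPM on glucose, from pH 5.5 to 3.5. Glycerol metabolism had 2 higher, 2 lower and 1 not passing, with GPD1 at 0.56 ± 0.05 and GUT1 at -0.05 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.598). GUT2 stood at -0.22 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.018) and at -0.12 without the 5 libraries that stood apart, where it did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0635).

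Citrate transport (1 higher, 2 lower), triacylglycerol synthesis and lipolysis (2 higher, 4 lower, 3 not passing), extracellular proteases and lipases (1, 2 and 1), hexose transporters (1, 0 and 3) and nitrogen assimilation (2, 2 and 1) moved in both directions or in few members. In them DGA1 changed by -0.61 ± 0.05, YHT4 by 1.41 ± 0.11, GLN1 by 0.70 ± 0.10 and GLT1 by -0.52 ± 0.08. In citrate transport the call of YHM2 (YALI0B10736g, -0.33) was lost in several fits that left out 1 library. Without DSM-21175 glycerol pH 5.5 replicate 2 YHM2 was at -0.28 (edgeR, Benjamini-Hochberg adjusted p = 0.0678). CTP1, the higher gene, was at 0.18, and at 0.12 without DSM-3286 glucose pH 5.5 replicate 3. Of 7 regulators and pH-related genes 1 rose and 6 fell. Of the 71 genes with a symbol 18 rose, 44 fell and 9 did not pass. YAS1 (YALI0C02387g), an activator of alkane-responsive genes, rose by 1.29 ± 0.13. Without a name, YALI0D19338g rose from 2.96 ± 0.694 to 1090 ± 102 CPM on glycerol in DSM-3286 and from 4.14 ± 1.47 to 968 ± 192 CPM on glucose in DSM-21175. YALI0D06688g went the other way, from 798 ± 42.3 to 0.637 ± 0.314 CPM on glycerol in DSM-21175. In all, 2236 genes rose and 2240 fell at pH 3.5, 174 and 326 of them at least 2-fold. The same sign in all 4 strata held for 3125 of the called genes (edgeR, Benjamini-Hochberg). On glycerol and on glucose the test called 4325 and 3027 genes within DSM-3286 and 1878 and 1783 within DSM-21175. Adjusted over the list alone, the counts were the same for every fixed list, and 18 rose and 45 fell among the genes with a symbol. Of 227 noncoding genes 83 fell and 3 rose at pH 3.5, with a median of -1.28. Their share of reads on glycerol in DSM-3286 was 0.0327 ± 0.0021% at pH 3.5 and 0.187 ± 0.025% at pH 5.5. In DSM-21175 it was 0.0573 ± 0.008 and 0.101 ± 0.01% on glycerol and 0.0407 ± 0.0076 and 0.0747 ± 0.034% on glucose, where replicate 3 at pH 5.5 had 0.113% against 0.06 and 0.051%.

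**Figure D3:**
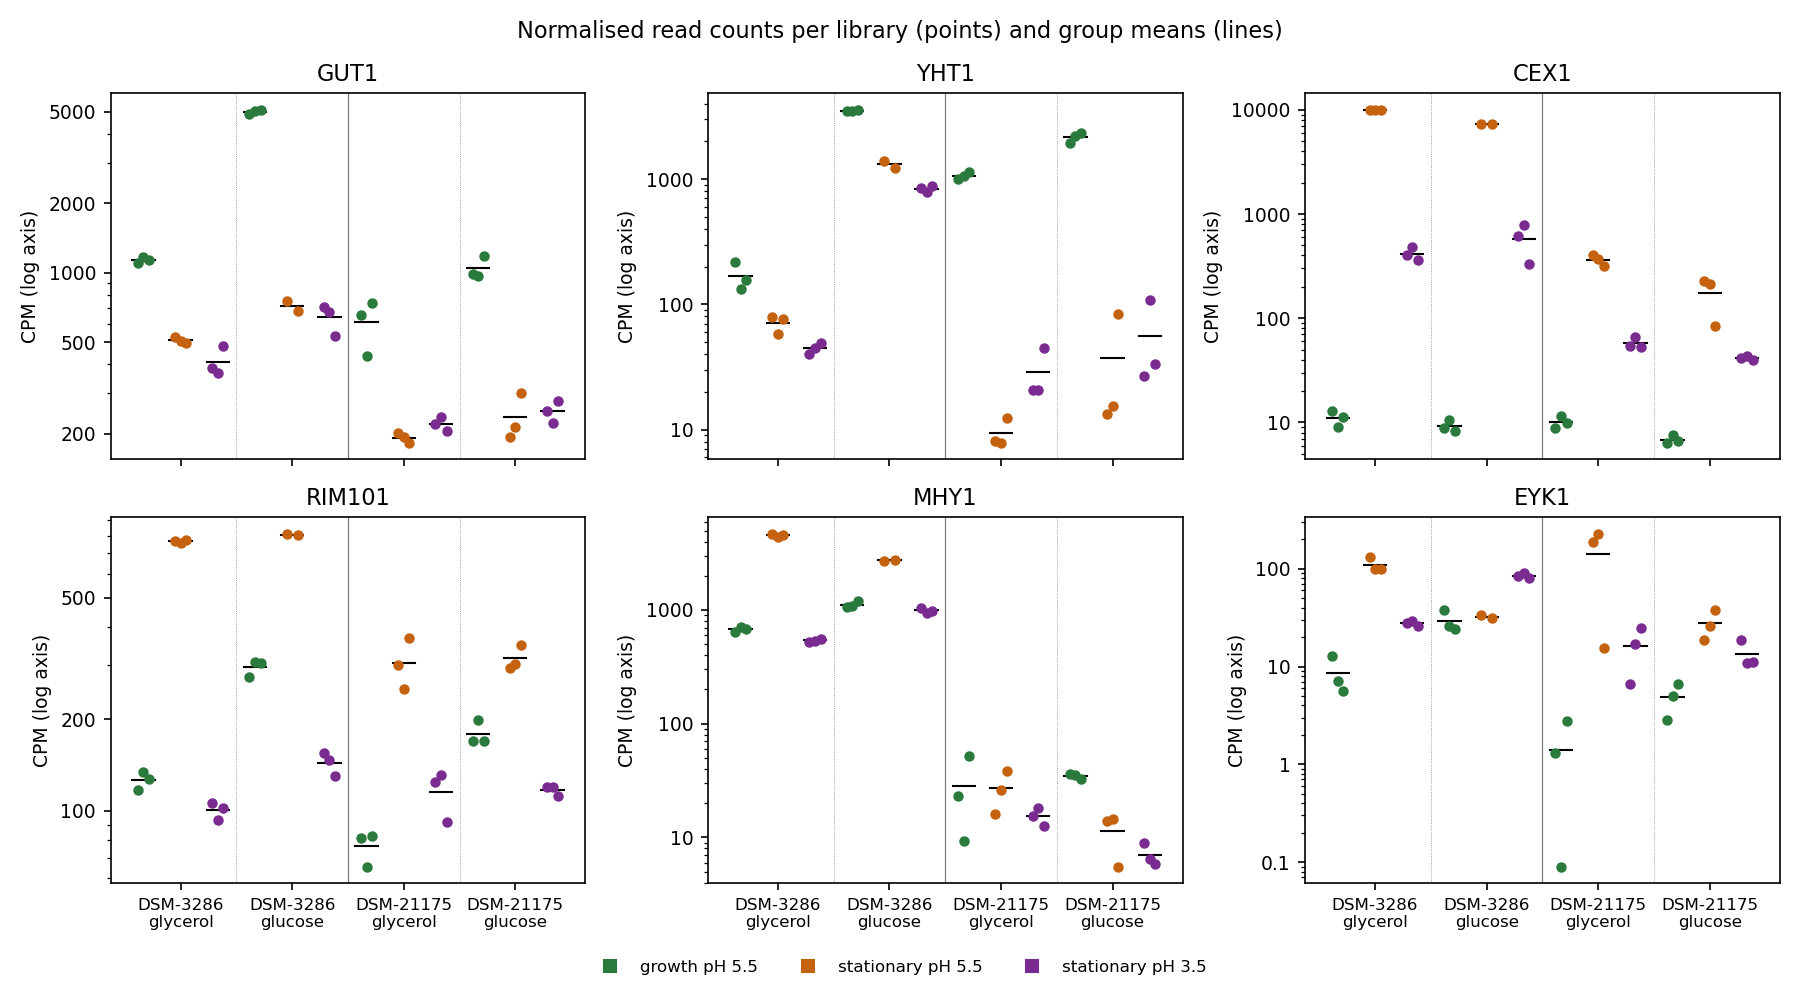
CPM of 6 genes on a log axis in every library, by strain and carbon source, with a point per library coloured by phase and pH and a line for the mean of each group. CEX1 lies between 9.28 and 11.1 CPM on average in growth phase of DSM-3286 and at 9900 CPM on glycerol at 32 h and pH 5.5, and MHY1 is lower in DSM-21175 than in DSM-3286 in all groups.

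The fourth comparison, stationary phase at 32 h against growth phase at pH 5.5, addresses the step into the stationary phase that the labels call nitrogen-limited. The phases also differ in hours and culture age, and the comparison does not part these from nitrogen. CEX1 rose from 11.1 ± 1.92 to 9900 ± 21.4 CPM on glycerol in DSM-3286 (SD, n = 3 each) and from 10.2 ± 1.36 to 364 ± 43.8 CPM in DSM-21175. Its log2 fold change over the 4 strata was 7.31 ± 0.17 (edgeR, Benjamini-Hochberg adjusted p = 2.12e-24). The hexose transporter genes YHT4 and YHT1 changed by -4.09 ± 0.12 and -3.83 ± 0.30, and GUT1 by -1.94 ± 0.08. The intracellular lipase gene TGL3 rose by 2.20 ± 0.06 and the acyltransferase gene DGA2 (YALI0D07986g) by 1.20 ± 0.05. Pyruvate kinase PYK1 (YALI0F09185g) changed by -1.37 ± 0.07 and enolase ENO1 (YALI0F16819g) by -1.35 ± 0.07.

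Of 13 genes of glycolysis and gluconeogenesis 11 fell in stationary phase and 2 did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.0296; adjusted p = 0.547 with an estimated correlation). In the tricarboxylic acid cycle and pyruvate entry 11 of 15 fell, 2 rose and 2 did not pass, with pyruvate dehydrogenase PDB1 (YALI0E27005g) at -1.46 ± 0.06 and pyruvate carboxylase PYC1 (YALI0C24101g) at 1.11 ± 0.09 (camera adjusted p = 0.0434, limma with Benjamini-Hochberg; adjusted p = 0.743 with an estimated correlation). This list did not pass without DSM-21175 glycerol growth replicate 1 (adjusted p = 0.0561) or glucose pH 5.5 replicate 3 (0.0516), nor without DSM-3286 glycerol growth replicate 2 (0.0503) or glucose pH 5.5 replicate 3 (0.0504; limma's camera, Benjamini-Hochberg). In triacylglycerol synthesis and lipolysis 7 of 9 rose and 2 did not pass (camera adjusted p = 0.0333, limma with Benjamini-Hochberg; adjusted p = 0.296 with an estimated correlation). In beta-oxidation 10 of 12 rose and 2 did not pass, with POX2 (YALI0F10857g) at 2.66 ± 0.11 and POX5 at 2.07 ± 0.17 (camera adjusted p = 0.0434, limma with Benjamini-Hochberg; adjusted p = 0.547 with an estimated correlation). This list call was lost without DSM-21175 glucose pH 5.5 replicate 3 (limma's camera, Benjamini-Hochberg adjusted p = 0.0507). The change of POX5 differed between the strains by -5.07 (DSM-21175 minus DSM-3286). On glucose POX5 rose with phase in DSM-3286 and was lower at 32 h than in growth phase in DSM-21175. Of the 12 cytochrome P450 genes 9 rose, 1 fell and 2 did not pass (camera adjusted p = 0.0296, limma with Benjamini-Hochberg; adjusted p = 0.296 with an estimated correlation). ALK12 (YALI0A20130g) rose by 5.04 ± 0.10 and ALK2 (YALI0F01320g) by 5.2 ± 0.37, or 6.03 without DSM-21175 glucose growth replicate 3.

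The other lists did not pass (limma's camera, Benjamini-Hochberg adjusted p between 0.164 and 0.741). Citrate transport had 1 gene higher and 2 lower, CEX1 against CTP1 at -2.45 ± 0.06 and YHM2 (YALI0B10736g) at -0.99 ± 0.14, so its median was -0.99 and its mean 1.29. In erythritol and mannitol metabolism 7 of 10 rose, 2 fell and 1 did not pass, with the mannitol dehydrogenase gene SDR1 (YALI0B16192g) at 2.24 ± 0.19 and EYK1 at 3.30 ± 0.35. EYI2 and EYD1 rose by 3.21 ± 0.35 and 3.43 ± 0.43, and by 3.87 and 4.06 without DSM-21175 glycerol growth replicate 3. Fatty acid synthesis had 3 higher, 5 lower and 2 not passing, with ATP-citrate lyase ACL1 (YALI0E34793g) at -1.28 ± 0.05 and the stearoyl desaturase gene OLE1 (YALI0C05951g) at 0.88 ± 0.05. Glycerol metabolism had 0 higher, 4 lower and 1 not passing, with GUT2 at -1.07 ± 0.08. In nitrogen assimilation 4 rose, among them GLT1 at 1.07 ± 0.08, and 1 fell, glutamate dehydrogenase GDH1 (YALI0F17820g) at -1.10 ± 0.08. The glyoxylate cycle (2 higher, 3 lower) held CIT2 at -2.93 ± 0.14 and MLS1 at 1.15 ± 0.09. The pentose phosphate pathway had 2 higher and 5 lower. Hexose transporters had 1 higher, 2 lower and 1 not passing. Of 4 extracellular protease and lipase genes 2 rose and 2 fell, with AXP1 at 1.59 ± 0.10 and LIP2 (YALI0A20350g) at -2.96 ± 0.22.

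Of 7 regulators and pH-related genes 5 rose in stationary phase and 2 fell, with RIM101 at 1.72 ± 0.06, the repressor gene MIG1 (YALI0E07942g) at 1.29 ± 0.09 and the plasma membrane proton ATPase gene PMA1 (YALI0B22066g) at -1.06 ± 0.05. Of the 71 genes with a symbol 39 rose, 19 fell and 13 did not pass, and SWI5 (YALI0E16973g) changed by -3.26 ± 0.08. Without a name, YALI0D04356g rose from 1.19 ± 0.469 to 7760 ± 352 CPM on glycerol in DSM-3286 and from 2.01 ± 0.465 to 2060 ± 650 CPM on glucose in DSM-21175. YALI0B16522g fell by 8.16 ± 0.17 on the log2 scale. In all, 2802 genes rose and 2826 fell, 1403 and 1032 of them at least 2-fold. Of the called genes 4118 had the same sign in all 4 strata (edgeR, Benjamini-Hochberg). By stratum the test called 4700 to 5206 genes. Adjusted over the list alone, the counts were the same for every list except glycerol metabolism (1 higher, 4 lower). Of 227 noncoding genes 53 rose and 40 fell, with a median of 0.39.

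The fifth comparison set DSM-21175 against DSM-3286 over the 6 culture conditions. MHY1 was lower in DSM-21175 in all of them, for instance at 27.0 ± 11.2 against 4520 ± 151 CPM on glycerol at 32 h and pH 5.5 (SD, n = 3 each). Its log2 fold change was -6.19 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p = 8.41e-21). CEX1 reached 175 ± 79.6 CPM in DSM-21175 and 7280 ± 11.5 CPM in DSM-3286 on glucose at 32 h and pH 5.5, with a mean over conditions of -2.89 ± 0.11. The cytochrome P450 gene ALK7 (YALI0A15488g) was at 9.71 ± 0.988 against 9160 ± 415 CPM on glycerol at 32 h and pH 5.5. The genes FAS1 (-1.61 ± 0.07), GUT1 (-1.40 ± 0.06) and PCK1 (-1.72 ± 0.09) were lower in DSM-21175.

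All 10 fatty acid synthesis genes tested were lower in DSM-21175, with acetyl-CoA carboxylase ACC1 (YALI0C11407g) at -1.19 ± 0.06 and fatty acid synthase subunit FAS2 (YALI0B19382g) at -1.18 ± 0.07 (limma's camera, Benjamini-Hochberg adjusted p = 0.000304; adjusted p = 0.0707 with an estimated correlation). All 5 genes of glycerol and dihydroxyacetone metabolism were lower, with DAK2 at -2.55 ± 0.23, DAK1 at -1.76 ± 0.06, GPD1 at -1.15 ± 0.04 and GUT2 at -0.96 ± 0.07 (camera adjusted p = 0.00301, limma with Benjamini-Hochberg; adjusted p = 0.111 with an estimated correlation). In glycolysis 10 of 13 were lower, 1 higher and 2 did not pass, with glyceraldehyde-3-phosphate dehydrogenase TDH1 (YALI0C06369g) at -1.24 ± 0.04 (camera adjusted p = 0.0033, limma with Benjamini-Hochberg; adjusted p = 0.231 with an estimated correlation). In the tricarboxylic acid cycle 13 of 15 were lower, 1 higher and 1 did not pass, with PDB1 at -1.03 ± 0.05 and PYC1 at -0.98 ± 0.07 (camera adjusted p = 0.00301, limma with Benjamini-Hochberg; adjusted p = 0.315 with an estimated correlation). In beta-oxidation 11 of 12 were lower and 1 higher, with POX4 at -1.50 ± 0.12 (camera adjusted p = 0.00221, limma with Benjamini-Hochberg; adjusted p = 0.231 with an estimated correlation). In the glyoxylate cycle 4 of 5 were lower, with CIT2 at -1.71 ± 0.11 and MDH2 (YALI0E14190g) at -1.43 ± 0.04. In triacylglycerol metabolism 7 of 9 were lower and 2 higher, with DGA1 at -1.30 ± 0.04 (camera adjusted p = 0.0419 for each, limma with Benjamini-Hochberg; adjusted p = 0.231 with an estimated correlation for each).

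The cytochrome P450 list did not pass, with 2 genes higher, 6 lower and 4 not passing (limma's camera, Benjamini-Hochberg adjusted p = 0.0534). It passed without any of 6 single libraries, at 0.0422 without DSM-21175 glucose pH 5.5 replicate 3, 0.0435 without glucose growth replicate 3, 0.0432 without glycerol pH 5.5 replicate 2, 0.0485 without glucose pH 5.5 replicate 1 and 0.0461 without glycerol pH 3.5 replicate 2 of that strain, and 0.0469 without DSM-3286 glycerol pH 5.5 replicate 1. The remaining lists did not pass (limma's camera, Benjamini-Hochberg adjusted p between 0.0954 and 0.801). Erythritol and mannitol metabolism had 1 gene higher, 7 lower and 2 not passing, with the erythrose reductase gene ER27 (YALI0F18590g) at -2.49 ± 0.05. The pentose phosphate pathway had 2 higher and 5 lower, citrate transport 1 higher and 2 lower, extracellular proteases and lipases 0 higher, 3 lower and 1 not passing, and nitrogen assimilation 1 higher, 2 lower and 2 not passing. Among these, LIP7 (YALI0D19184g, -1.06) lost its call on the deposited log2 values (-0.21, limma, Benjamini-Hochberg adjusted p = 0.181). GLN1, the higher gene of nitrogen assimilation (0.18), lost its call with RLE scaling (edgeR, Benjamini-Hochberg adjusted p = 0.0655) and with DESeq2 (Benjamini-Hochberg adjusted p = 0.0546). Among the 35 fits that left out 1 library, the call of LIP7 was lost in 11 and that of GLN1 in 25. Of 4 hexose transporter genes 2 were higher and 2 lower. The call of YHT2, higher by 2.06, was lost without DSM-21175 glycerol pH 3.5 replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 1). The median of the 4 was 0.37, and -0.43 on the deposited log2 values, with YHT3 (YALI0F19184g) at 1.75 ± 0.16 and YHT1 at -1.77 ± 0.21. Of 7 regulators and pH-related genes 6 were lower and 1 did not pass, with PMA1 at -1.09 ± 0.04 and RIM101 at -0.70 ± 0.05.

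Among genes with a symbol in the deposited log2 table, AZF1 (-6.24 ± 0.17), MSN4 (YALI0C13750g, -3.24 ± 0.08), a stress-response zinc finger gene in budding yeast, and NRG1 (YALI0C12364g, -3.18 ± 0.13) were lower in DSM-21175. Genes higher were RME1 (YALI0E17215g, 2.30 ± 0.24), CHA4 (YALI0C15202g, 1.07 ± 0.07), ARO80 (YALI0C18645g, 1.06 ± 0.07), OPI1 (YALI0C14784g, 1.05 ± 0.10) and JJJ1 (YALI0B15312g, 0.94 ± 0.05). Of the 71 such genes 25 were higher, 34 lower and 12 did not pass. YALI0B08712g had 127 to 171 CPM in the groups of DSM-3286 and at most 1 read in any library of DSM-21175. YALI0E02178g had 21.1 ± 8.36 CPM over the 18 libraries of DSM-21175 and 0 reads in the 17 of DSM-3286. YALI0D14872g was higher in DSM-21175 by 5.22 ± 0.14. In all, 2810 genes were higher in DSM-21175 and 2449 lower, 374 and 772 of them at least 2-fold. Of the called genes 2571 had the same sign in all 6 conditions (edgeR, Benjamini-Hochberg). By condition the test called 3196 to 4559 genes. Adjusted over the list alone, the counts were the same for every list except nitrogen assimilation (0 higher, 2 lower). Of 227 noncoding genes 81 were lower in DSM-21175 and 11 higher, with a median of -1.28 (-0.75 on the deposited log2 values). Their share of reads went the other way at pH 3.5 (0.0407 against 0.0213% on glucose and 0.0573 against 0.0327% on glycerol) and was lower in DSM-21175 on glycerol at pH 5.5 (0.101 against 0.187% at 32 h and 0.0683 against 0.0937% in growth phase). On glucose at pH 5.5 it was 0.0747 against 0.064% at 32 h and 0.048 against 0.047% in growth phase. The 5 libraries that stood apart all belong to this strain. Sequence differences between a strain and the genome used for counting can lower its counts, and the genome is not named in the sources used here.

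**Figure D4:**
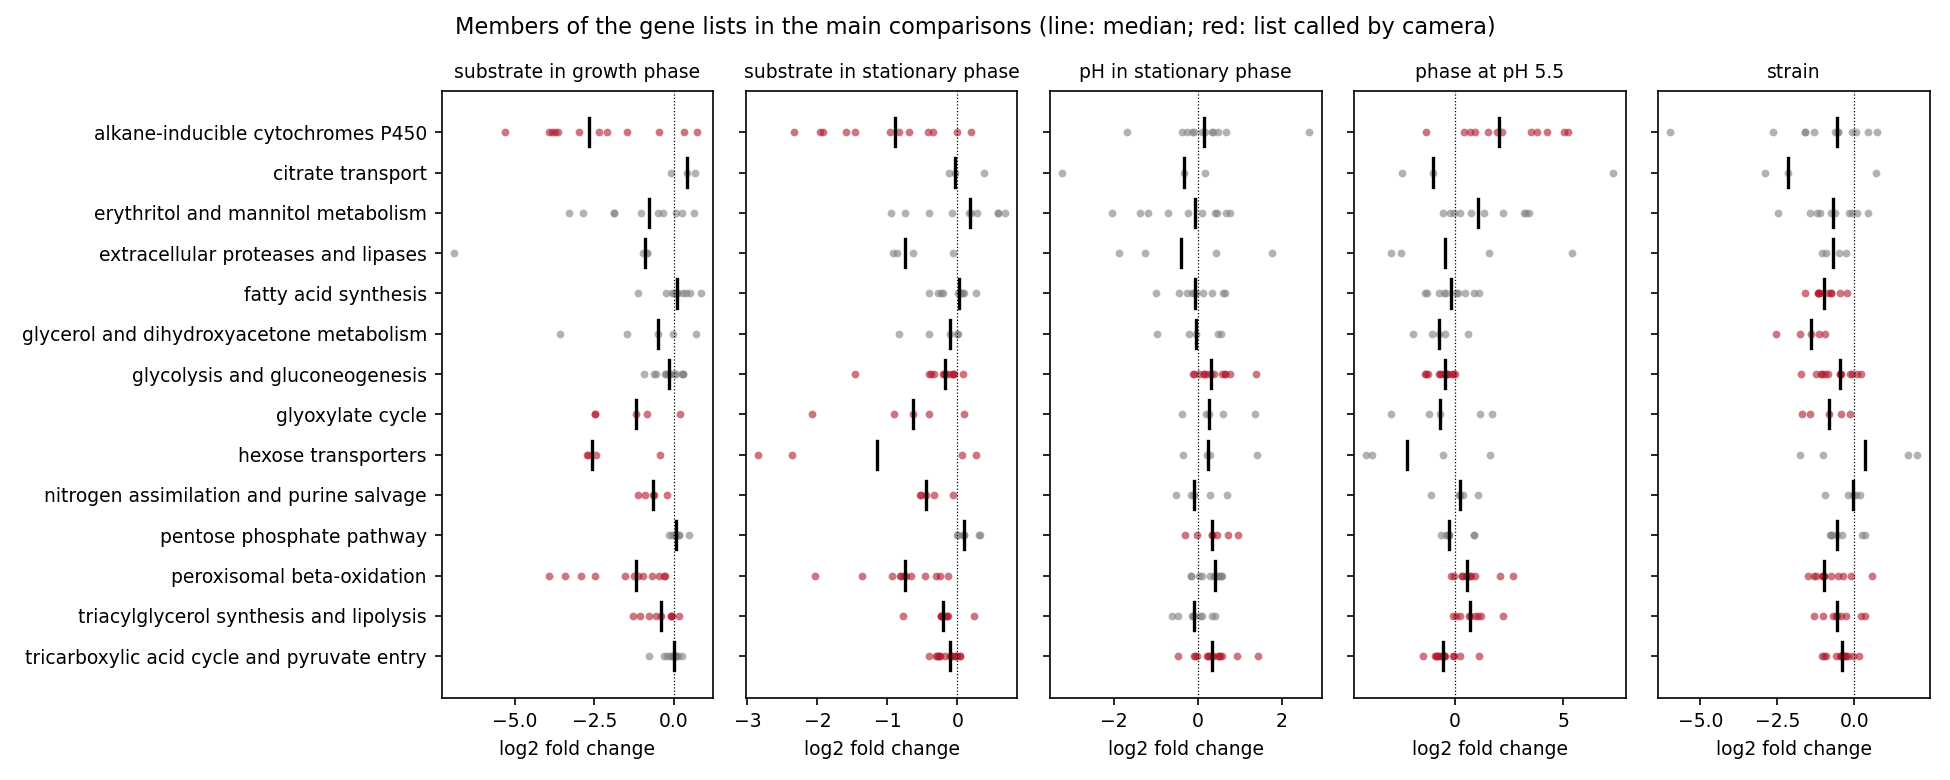
Log2 fold changes of the members of 14 fixed gene lists in the 5 comparisons, with a point per gene, a line for the median and red points where the list passed limma's camera test. Peroxisomal beta-oxidation, for example, has medians of -1.18 and -0.75 for glycerol against glucose in growth and stationary phase and of 0.57 for stationary against growth phase.

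The design also asks whether one factor changes the effect of another, which was tested as a difference of fold changes. At pH 5.5, the effect of carbon source differed between phases for 3202 genes, 784 of them at least 2-fold. The effect of pH differed between glycerol and glucose for 1272, 208 of them at least 2-fold (edgeR, Benjamini-Hochberg). The effect of carbon source differed between the strains for 642 genes in growth phase and 2031 at 32 h, that of pH for 2680 and that of phase for 3807, of which 303, 300, 472 and 1217 were at least 2-fold (edgeR, Benjamini-Hochberg). Without the 5 libraries that stood apart, the pH effect differed between glycerol and glucose for 2100 genes and the carbon source effect in growth phase differed between the strains for 1177 (edgeR, Benjamini-Hochberg). On glucose ALK7 was at 148 ± 9.93 CPM in growth phase and 4650 ± 582 CPM at 32 h and pH 5.5 in DSM-3286, and at 9.16 ± 0.968 and 33.3 ± 35.7 CPM in DSM-21175 (SD, n = 3 each, 2 for DSM-3286 at 32 h), where ALK7 ranged from 11.8 to 74.5 CPM between the 32 h replicates of DSM-21175. On glucose AXP1 was at 10.5 ± 1.30 CPM at pH 3.5 and 50.7 ± 16.5 CPM at pH 5.5 in DSM-3286. In DSM-21175 it was at 14.8 ± 0.471 and 21.5 ± 6.10 CPM. DAK2 on glycerol in DSM-3286 was at 11.1 ± 2.28 CPM in growth phase and 62.6 ± 1.69 CPM at 32 h and pH 5.5. On glucose it was at 137 ± 7.47 and 68.6 ± 9.64 CPM.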

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

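Of the tests in this part, the fits without the 5 libraries that stand apart and the tests of RNA from DSM-3286, of 4 libraries belonging to another group, of a time shift for YHT1 and YHT4, of random carryover and of mitochondrial RNAs were chosen after the result was seen.

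The results below were singled out because a change differed between phases, carbon sources or strains in a test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The change with carbon source differed between phases for 3202 genes and the change with pH differed between carbon sources for 1272. Between strains, 642 genes differed in the change with carbon source in growth phase, 2031 in that at 32 h, 2680 in that with pH and 3807 in that with phase. Without the 5 libraries that stand apart the 1272 became 2100 and the 642 became 1177. Among genes named in the comparisons, 22 of 61, 33 of 60, 28 of 61 and 46 of 63 differed between strains for carbon source in growth phase, carbon source at 32 h, pH and phase. Of all genes tested, 9.8, 31.1, 41 and 58.2% did. The named genes were mostly picked for large changes in these same data, so their counts are not evidence about a set. In DSM-21175 the change was smaller or of opposite sign for 21, 23, 23 and 22 of those that differed, in that order.

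The following values are log2 differences. At 32 h and pH 5.5 the change on glycerol was lower than in growth phase for GPD1 (-0.89) and PCK1 (-1.79). That change was also lower for BUD20 (-1.02), KAP122 (YALI0E29909g, -0.87) and TFC2 (-1.40). It was higher for LIP8 (6.15), DAK2 (3.82), EYK1 (3.94), EYI2 (4.99) and EYD1 (4.04). Without DSM-21175 glycerol growth replicate 3, EYI2 was at 6.31 and EYD1 at 5.29. The change at pH 3.5 was lower on glycerol than on glucose for SWI5 (-2.50), DAK2 (-2.19), EYK1 (-2.77), EYI2 (-3.55) and EYD1 (-4.29, or -4.91 without DSM-21175 glycerol pH 3.5 replicate 3). It was higher for YAS1 (1.42), PCK1 (1.21), CIT2 (2.11), HAP1 (YALI0F17424g, 0.88) and ALK9 (0.83). The call of ALK9 was lost in 9 of the 23 fits that left out 1 library, for instance at 0.67 without DSM-21175 glucose pH 5.5 replicate 3.

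For carbon source in growth phase, the change was lower in DSM-21175 for IXR1 (-1.17), STP3 (-1.48), REI1 (-0.56), GZF1 (YALI0D20482g, -1.78) and TAL1 (YALI0F15587g, -0.49). It was higher for ALK7 (4.37), ALK12 (3.05), LIP2 (2.96), YHT1 (3.36) and ALK3 (3.25). The call of REI1 was lost in 11 of the 12 fits that left out 1 library, at -0.42 without DSM-21175 glucose growth replicate 3. That of GZF1 was lost at -0.95 without DSM-21175 glucose growth replicate 1. Both were lost with only the libraries compared (edgeR, Benjamini-Hochberg adjusted p = 0.0651 and 0.186 in that order) and with limma on the deposited log2 values (0.0537 and 0.103), and REI1 without a filter (edgeR, 0.0705). At 32 h it was lower for ALK7 (-1.39), MLS2 (-2.01), LIP7 (YALI0D19184g, -1.99), YOX1 (YALI0E20449g, -1.52) and ALK1 (-1.50) and higher for YHT1 (2.74), DAK2 (1.45), YHT4 (2.22), EYI2 (2.45) and EYD1 (2.64). Without DSM-21175 glucose pH 5.5 replicate 3, ALK7 was at -0.70, MLS2 at -1.41, LIP7 at -1.08 and YHT1 at 3.43. ALK1 and DAK2 each lost their call in 17 of the 23 fits that left out 1 library. With only the libraries compared ALK1 and DAK2 were lost too (edgeR, Benjamini-Hochberg adjusted p = 0.0997 and 0.0681), DAK2 also without a filter (edgeR, 0.0519) and with DESeq2 (0.0535), and EYD1 with limma on the deposited log2 values (0.0934). ALK1 was at -2.14 without DSM-21175 glycerol pH 3.5 replicate 2, DAK2 was at 1.17 without DSM-21175 glycerol pH 5.5 replicate 2, and EYD1 was at 2.02 without DSM-21175 glycerol pH 3.5 replicate 3.

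The change at pH 3.5 was lower in DSM-21175 than in DSM-3286 for IXR1 (-1.49), TYE7 (YALI0C13178g, -2.33), YHT4 (-2.0), EYI1 (YALI0F01584g, -1.28) and EYK1 (-1.79). It was higher for AXP1 (2.48), MHY1 (1.52), YHT1 (1.73), LIP7 (4.40) and CEX1 (1.75). Without DSM-21175 glucose pH 5.5 replicate 3, TYE7 was at -1.73, YHT1 at 2.44 and LIP7 at 5.33. The change from growth to stationary phase was lower in DSM-21175 for ALK7 (-6.67), YHT1 (-5.00), POX5 (-5.07), CEX1 (-4.79) and POX1 (-4.67). Without the same library ALK7 was at -7.44 and YHT1 at -5.77. It was higher for HOY1 (YALI0A18469g, 1.94), GZF1 (2.56), ALK2 (5.2, or 6.85 without DSM-21175 glucose growth replicate 3), EYK1 (2.72) and EYD1 (2.01). The call of EYD1 was lost in 18 of the 23 fits that left out 1 library, at 1.68 without DSM-21175 glycerol growth replicate 2, and its value was 3.26 without DSM-21175 glycerol growth replicate 3. It was also lost with RLE scaling, no filter, only the libraries compared and DESeq2 (Benjamini-Hochberg adjusted p = 0.05, 0.0513, 0.0756 and 0.0546, edgeR except the last) and with limma (Benjamini-Hochberg adjusted p = 0.109).

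Regrouping the libraries within strata 100 times, the labels included, tested whether chance can give such counts. For carbon source in growth phase and at 32 h, pH, phase and strain, 1 of 100 regroupings, the labels themselves, gave as many genes, with 2438, 951, 2605, 3835 and 1961 genes in the highest of the others against 4089, 2823, 4476, 5628 and 5259. For substrate by phase, strain by substrate at 32 h and strain by phase it was again 1, with 1622, 1845 and 3058 in the highest other. For substrate by pH it was 4, with 2597 against 1272 in the highest other, for strain by substrate in growth phase 2, with 768 against 642, and for strain by pH 3, with 4583 against 2680. For carbon source in growth phase and at 32 h, pH, phase and strain, labels unrelated to expression are excluded at a share of 0.05. For the differences of changes the regroupings cannot decide. Exchanging labels removes the main change together with the difference, so the absence of a difference alone was not tested. Exchanging labels inside 1 stratum turns a main change into a difference between strata, so the regroupings above the labels point to the structure of the samples.

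A first pattern is the genes lower on glycerol in growth phase, where glucose was sampled at 12 h and glycerol at 8 h. The hexose transporter genes YHT1 and YHT4 were lower at 32 h than in growth phase, with -3.83 as the higher of their changes. Glucose libraries further towards the 32 h state would thus have less of both, while both were higher on glucose. This argues against such a shift as the cause of the lower level of YHT1 and YHT4 on glycerol. It cannot show that no shift took place, since a stronger effect of carbon source could hide it. The other genes of the pattern are not covered. YHT3, which rose by 1.64 with phase, was not called lower on glycerol in growth phase. A change between 8 h and 12 h that does not follow the step to 32 h was not tested, as no carbon source was sampled at both hours. Of the 623 genes at least 2-fold lower, 78.2% were also below 0 at 32 h, in other libraries and with equal hours, which is consistent with an effect of carbon source itself. Across genes, the carbon source change in 1 strain correlated with the phase change in the other at r = -0.24 and -0.40, where genes are not independent replicates, so that a part from a time shift stays open.

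A second pattern is the 5 libraries of DSM-21175 apart from their replicates. All but the glycerol growth library are replicate 3. The deviations of the 5 from their replicates correlated pairwise across genes at an absolute r of 0.1 to 0.49, positive in 6 of 10 pairs. A cause common to libraries of the same replicate number was not tested. Genes read in DSM-3286 and hardly in the other libraries of DSM-21175, chosen without these 5, stood in them at 0% of their DSM-3286 level (6 genes), which argues against RNA of the other strain. The deviations of the 5 libraries had a median absolute correlation of 0.04 with the pH change in DSM-3286, which argues against a shift along that change. A shift along the pH change of DSM-21175 itself, which differed from it for 2680 genes, was not tested. Of the 4 libraries other than the glycerol one at pH 3.5, 0 correlated best with another group, while that library had a mean r of 0.9829 with glucose at pH 3.5 and 0.9791 with its own group. It lay at 0.59 on a scale from glucose (0) to glycerol (1) over 434 genes, with its replicates at 0.87 and 0.96 and the glucose libraries between -0.03 and 0.06, so a mixed or mislabelled sample stays open for it. This position was computed because that correlation, run first over all 5 libraries, had singled it out.

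The last pattern is the noncoding RNAs, higher on glycerol and lower at pH 3.5. Of the variance of their log2 share of reads, 94.2% lay between groups. The pattern was picked for its differences between groups in the same libraries, so this share restates it and cannot decide on carryover that varies at random. Coding genes of the same range of expression had a median of -0.22 at 32 h (347 genes) and mitochondrial genes one of -0.20 (15 genes), against 1.61 for the noncoding genes (0.87 on the deposited log2 values), which for carbon source argues against a change common to genes with few reads or little poly(A). For pH, mitochondrial genes had a median of -0.71 beside -1.28 for the noncoding genes, so that a change common to RNAs with little poly(A) stays open there. A difference in RNA handling between groups may remain, and a change in the cells stays a hypothesis found and tested on the same data.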

How the results depend on the processing

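The fits without the 5 libraries of DSM-21175 that stand apart were chosen after seeing the data; all other alternatives were planned. No list call or named gene changed direction. Which of higher and lower was the larger count did change under at least 1 alternative in every contrast except strain by substrate in growth phase, and for strain only with the 2-fold condition (374 higher and 772 lower, against 2810 and 2449). Carbon source in growth phase went from 2081 higher and 2008 lower to 1887 and 2281 with RLE, 1895 and 2332 with DESeq2 and 1842 and 2326 without a filter. Substrate by phase went from 1504 and 1698 to 1773 and 1464 with RLE, and strain by pH from 1366 and 1314 to 1276 and 1610 on the deposited log2 values. On the deposited log2 values, medians moved by over 1.5 times for the cytochromes P450 (-2.67 to -1.49), the hexose transporters (-2.58 to -1.37), citrate transport (0.41 to 0.26) and the noncoding genes (1.16 to 0.63) for carbon source in growth phase. They did so too for the noncoding genes at 32 h (1.61 to 0.87) and between strains (-1.28 to -0.75), the extracellular proteases and lipases with phase (-0.45 to -0.29) and the hexose transporters between strains, with a change of sign (0.37 to -0.43), where the latter 2 and citrate transport are lists that did not pass. Some smaller medians did so as well, for pH among them the hexose transporters (0.26 to 0.1) and the cytochromes P450 (0.15 to 0.06). For carbon source in growth phase the pentose phosphate pathway was such a case (0.09 to 0.03). These lists did not pass there either. RLE scaling, no expression filter, DESeq2, limma on the deposited log2 values and a fit of only the libraries compared each kept the counts of the 11 contrasts within 1.5 times. The median log2 fold change of all genes moved most for substrate by phase, from 0.024 to 0.089 with RLE scaling. Requiring a 2-fold change as well left 984, 310, 500, 2435 and 1146 genes for carbon source in growth phase and at 32 h, pH, phase and strain, and 784, 208, 303, 300, 472 and 1217 for substrate by phase, substrate by pH, strain by substrate in growth phase and at 32 h, strain by pH and strain by phase; fewer genes pass a second condition by construction. Without the 5 libraries, substrate by pH rose from 1272 to 2100 genes and strain by substrate in growth phase from 642 to 1177, and the other contrasts stayed within 1.5 times; the cause was not tested.

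Leaving out 1 library at a time gave 3876 to 4046, 2648 to 2982, 4290 to 4515, 5565 to 5634 and 5174 to 5279 genes for the 5 comparisons, and 2972 to 3227, 1006 to 1472, 475 to 874, 1769 to 2248, 2346 to 2851 and 3593 to 3783 for the 6 differences, in the order above. It gave 27 to 30 list calls against 29 and 360 to 367 named results against 369 of 375. Where it leaves 1 library in DSM-3286 on glucose at pH 5.5, that library is assumed to vary like the other groups. Of the 29 list calls, 3 passed with an estimated correlation. Named results passing were 366 with RLE, 364 without a filter, 364 with DESeq2, 361 with limma, 358 with only the libraries compared and 365 without the 5 libraries.

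The replicate numbers do not pair the libraries throughout: the correlation of same-numbered deviations was over 0.1 in 1 of 6 pairs for carbon source in growth phase, 3 of 11 at 32 h, 1 of 11 for pH, 3 of 11 for phase and 2 of 17 for strain. All 3 pairs were over 0.1 in DSM-21175 for phase on glucose (0.35, 0.34 and 0.45) and for carbon source at pH 5.5 (0.17, 0.19 and 0.35), and all 3 were below 0 in DSM-21175 for pH on glycerol (-0.22, -0.30 and -0.49). In these 3 strata replicate 3 of both groups stands apart. With a replicate block the counts were 4063, 2790, 4453, 5623 and 5250, and 5547 for phase with the block within strain and carbon source. The block left 29 list calls, with the pentose phosphate pathway at pH 3.5 lost and the cytochromes P450 between strains gained (limma's camera, Benjamini-Hochberg adjusted p = 0.0505 and 0.0483), and 366 named results. With the block EYD1 in strain by phase (0.0602), DAK2 in strain by substrate at 32 h (0.0504), MLS1 for pH (0.0596) and GLN1 between strains (0.0519) did not pass, and CEX1 for carbon source in growth phase did (0.0364, edgeR with Benjamini-Hochberg adjusted p for each).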

Other observations

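The genes with reads in 1 strain were chosen after their values were seen, and no explanation is tested in this part.

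Some genes followed phase, strain and carbon source together. SWI5, named in the deposited log2 table, was at 119 ± 5.50 CPM on glucose and 95.3 ± 2.43 CPM on glycerol in growth phase of DSM-3286, and at 13.8 ± 1.22 and 69.4 ± 4.32 CPM at 32 h and pH 5.5 (SD, n = 3, and 2 for glucose at 32 h). In DSM-21175 it was at 106 ± 5.17 and 89.9 ± 9.05 CPM in growth phase and 3.65 ± 0.835 and 3.66 ± 1.01 CPM at 32 h. MSN4 went from 93.6 ± 2.27 to 638 ± 61.3 CPM on glycerol in DSM-3286 and from 53.9 ± 1.01 to 22.3 ± 2.15 CPM in DSM-21175. The acyl-CoA oxidase gene POX5 went from 17.2 ± 2.28 to 125 ± 15.3 CPM on glucose in DSM-3286 and from 113 ± 50.2 to 50.6 ± 17.2 CPM in DSM-21175. ALK2 reached 1360 ± 580 CPM on glucose at 32 h and pH 5.5 in DSM-21175 and 241 ± 20.6 CPM in DSM-3286.

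With at least 10 reads in every library of 1 strain and at most 3 over all libraries of the other, 6 genes were read in DSM-3286 and 1 in DSM-21175. In DSM-3286 these were YALI0B08624g (24.5 ± 10.6 CPM), YALI0B08690g (15.5 ± 3.05), YALI0B08712g (150 ± 17.1), YALI0F10824g (8.37 ± 6.16), YALI0A01562g (18 ± 6.91) and YALI0A01602g (17.8 ± 8.67; SD, n = 17 each). At their DSM-3286 level these genes would have 105 to 1870 reads in a library of DSM-21175, where they had 0, 0, 2, 1, 1 and 1 reads over 18 libraries. YALI0E02178g was at 21.1 ± 8.36 CPM in DSM-21175 (SD, n = 18) and had 0 reads over 17 libraries of DSM-3286. A missing gene and a diverged sequence were not told apart.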
